A study of Mus musculus with 15 samples.

How the data were processed

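RNA-seq libraries were made from leukemia stem cells (LSC) of gonadal adipose tissue (AT), bone marrow (BM), spleen (SPL) and peripheral blood (BL), collected 12 days after transplantation, and from their normal counterparts in bone marrow (NBM). There were 15 libraries, 3 in each of 5 groups, from female mice of 3 months. Per the labels, RNA was extracted with Qiagen RNeasy Plus, and libraries were made with Clontech SMARTer low-input chemistry and Illumina Nextera XT. The labels do not say whether the 3 libraries of a group came from separate mice, so the authors' p-values may measure technical spread. The labels give no sort gate for the LSC, so the share of other cells is not known from them.

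The authors trimmed reads with Trimmomatic 0.32 and used Cufflinks 2.0.2 and Cuffdiff on mm10. The aligner, the gene annotation and the version of Cuffdiff are not given in the sources used here. The authors deposited 1 pooled FPKM value per gene and group, the fragments assigned to a gene scaled by its length and the depth of sequencing, computed by Cuffdiff over the 3 libraries of the group. They also deposited the lower and upper bounds of each FPKM, which lie 2 standard deviations on either side. An estimated count per gene and group, the number of fragments Cuffdiff assigned to the gene, was deposited by the authors as well. For each of the 10 pairs of groups the authors deposited a Cuffdiff table with the log2 fold change, a test statistic, a p-value and a q-value for 23359 genes. The combined table of all pairs held the same entries as the 10 tables, apart from the FPKM columns, which were left out of that check. No column held the value of a single library.

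The files were checked before use. The deposited p-value equalled the normal tail probability of the test statistic to within 0.0001 in 100% of genes with a fold, a margin that does not test smaller p-values. The standard error that fold and statistic imply equalled the one from the deposited bounds within 1% in 99.6% or more of genes with bounds in each comparison. The q-value equalled a Benjamini-Hochberg adjustment over the tests of all 10 comparisons together, to within 1.70e-06, whereas an adjustment within a comparison differed by up to 0.693. Gene starts were counted from 0 in the files. Adding 1 made them equal to a GENCODE M21 transcript start for 10048 of 21636 genes matched by symbol, against 965 without, so coordinates are printed from 1 on mm10. Entries that merge genes (105) and genes whose FPKM differed between tables (129, counted for AT against BM LSC) were kept, and an alternative left them out. Folds with 0 in 1 group are infinite in the files and are not printed.

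The pooled columns held 1.95e+07 estimated counts for NBM, 1.65e+07 for BM, 8.96e+06 for SPL, 1.95e+07 for BL and 1.96e+07 for AT LSC. Genes at an FPKM of 1 or more numbered 8233, 8204, 8228, 7667 and 7540 in the same order. The 10 most abundant genes took 8.66%, 8.32%, 12.1%, 8.74% and 9.20% of the estimated counts. The median standard error of a log2 fold over tested genes ranged from 0.399 in BM LSC against NBM to 0.585 in AT against SPL LSC. The smallest fold called was 0.72 on the log2 scale in the former and 1.26 in the latter. Larger folds can be missed too, since 44% of simulated genes at a log2 fold of 2 were called in the latter. A gene not called is therefore not shown to be unchanged.

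The design, the gene lists and the rule for naming genes were fixed before the data were examined. A test of counts per replicate was planned, with values without a test and the authors' comparison tables copied as theirs as the fallback. Because the deposited columns are pooled, the fallback was used, and no test of replicates was computed here. A gene was called when the authors' table gave it a test and a q-value below 0.05. The difference between AT LSC and the other 3 sites, and between the 4 LSC groups and NBM, was taken as the genes called in the same direction in each of the comparisons involved. For folds of a gene against a group with 3 or fewer estimated counts, FPKM values are given in place of the fold.

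The genes named were, for AT against BM LSC and BM LSC against NBM, the 8 largest positive and 8 largest negative folds among called genes with a mean CPM (counts scaled to equal library size) of 16 or more over the 5 pooled columns. The other comparisons and the 2 shared sets, ranked by the mean of their folds, gave 5 in each direction. Up to 4 members of each list with the smallest q-value were added, as were Cd36, Tnf, Il1a, Il1b, Csf2, Cpt1a, Mki67, Kit, Hoxa9, Meis1, Myc and Cxcr4. Predicted genes were skipped, and a few genes that the rule picks are not reported here. The part of the rule that asked for groups without overlap between replicates could not be applied to pooled values. Other genes named, such as those followed from 1 comparison to the next, were chosen after their values were seen.

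The 29 gene lists held 463 gene symbols, of which 457 were found. They covered pathways, signs of RNA quality and handling, and markers of other cell types. For each list and comparison, members called higher and lower were counted, with a second adjustment over the list alone. The median log2 fold was compared with 10000 random lists of the same size, drawn from 20 bins of mean FPKM with a pseudocount of 0.1. Profiles were compared by Spearman correlation. Interval bounds on shares are Wilson bounds.

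The alternatives tried were other scalings (folds minus their median, upper quartile, total estimated counts), adjustment within the comparison, a q below 0.01, an absolute log2 fold of 1 or more, a mean CPM of 5 or more, no filter, merged entries left out, marker genes of other cell types left out, members of other lists left out and pseudocounts of 1 and 0.1. Scalings were applied to the folds with the deposited error and a new adjustment over all comparisons. The centring and the list ranking were tested on simulated data built from the deposited errors. An added shift of -0.5 was recovered within 0.05 in every comparison, and no called gene had the wrong sign. Of 100 simulated genes at a log2 fold of 4, 89% to 98% were called, and at 2, 44% to 82%. Of 1000 lists shifted by 1, 100% ranked in the top 5%, against 5.1% of unshifted lists. The simulations changed few genes, with random signs and independent errors. They do not test centring where many genes move in the same direction, or list ranks of genes that move together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.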

Results

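Leukemia stem cells (LSC) of a mouse model of blast-crisis chronic myeloid leukemia, driven by BCR-ABL and NUP98-HOXA9, were compared between 4 sites and with their normal counterparts. The sites were gonadal adipose tissue (AT), bone marrow (BM), spleen (SPL) and peripheral blood (BL), and the normal cells came from marrow (NBM). Each of the 5 groups had 3 RNA-seq libraries from female mice, but the deposited tables give 1 pooled value per group. All levels below are the authors' FPKM, and all folds and q values come from the authors' deposited table of each comparison. A gene was called when it was tested and its q was below 0.05. List counts give called members, and where no count adjusted over the list alone follows, it was the same. Folds are log2 of the first group over the second, and ± gives the standard error that the authors' own test statistic implies. The question behind the comparisons is which programs leukemia cells carry in adipose tissue and how these differ from other sites.

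The pooled profiles fell into 2 pairs. Across 8319 genes at an FPKM of 1 or more, BM and SPL LSC had a Spearman correlation of 0.952 and BL and AT LSC of 0.918. The remaining pairs were lower: NBM correlated with BM LSC at 0.873, with SPL LSC at 0.876, with AT LSC at 0.804 and with BL LSC at 0.758. AT LSC correlated with BM LSC at 0.823 and with SPL LSC at 0.763, and BL LSC with BM LSC at 0.782 and with SPL LSC at 0.713. These are correlations across genes, which are not independent replicates. In the authors' deposited table SPL against BM LSC had the fewest called genes, 324, and BL LSC against NBM the most, 4474.

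**Figure D1:**
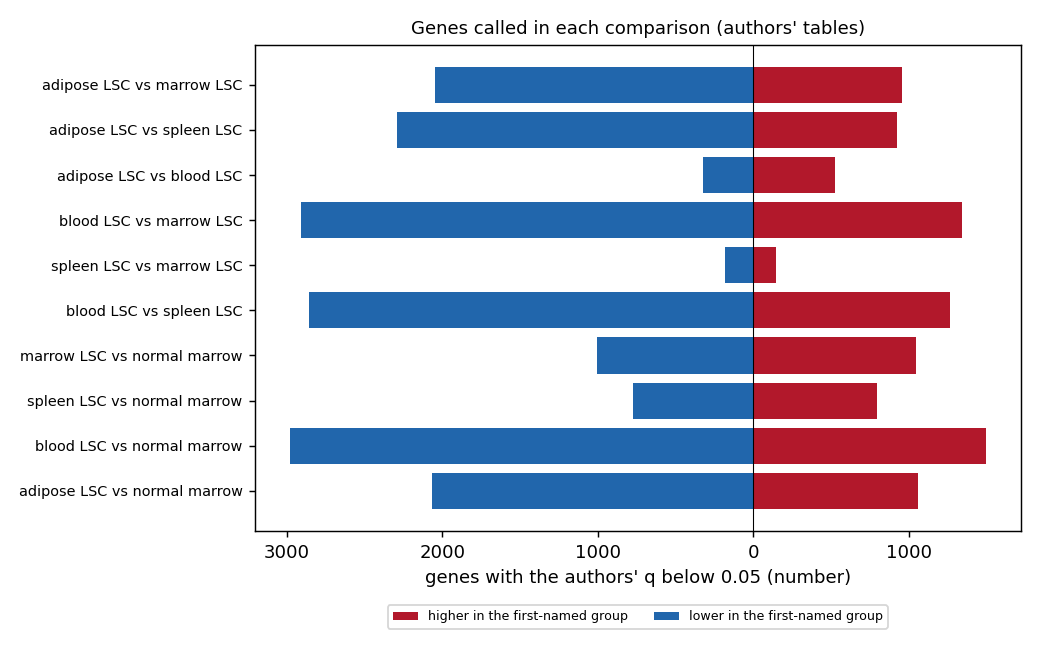
Genes called at q below 0.05 in each of the 10 comparisons of the authors' deposited table, with the number of genes on the x axis and bars to the right for genes higher and to the left for genes lower in the first-named group. SPL against BM LSC had 143 higher and 181 lower, and BL LSC against NBM had 1494 higher and 2980 lower.

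LSC from adipose tissue differed from marrow LSC in inflammatory cytokines, in lipid handling and in myeloid maturation genes. Csf2, which encodes the growth factor GM-CSF, Il1b and Il1a, which encode the forms of interleukin-1, and the neutrophil chemokine genes Cxcl1, Cxcl2 and Cxcl3 were all higher in AT LSC. So were Plin2, the coat of lipid droplets, Fabp4, a carrier of fatty acids in the cytosol, and Lpl, which frees fatty acids from lipoproteins. Genes of stem cells and of the erythroid, megakaryocyte and mast cell lineages were lower, among them Meis1, the partner of HOX proteins. Of 13160 tested genes, 2999 were called in the authors' deposited table, 953 higher and 2046 lower. The median fold of the tested genes was -0.48 (log2), and folds centred on it gave 1557 higher and 673 lower (1307 and 990 under total count scaling), so the balance of directions depended on the scaling. List medians in the comparisons that follow are therefore given relative to the median of all tested genes.

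The cytokine and chemokine list was higher in AT LSC, at 12 higher and 0 lower of 20 (14 and 0 adjusted over the list alone) in the authors' deposited table. Its median was 2.60, and 0 of 10000 random lists of genes of similar level had a median as high. Csf2 (chromosome 11, 54247270 to 54249899 in mm10, 1-based) stood at 79.8 FPKM in AT LSC and 6.0 in BM LSC, a fold of 3.73 ± 0.52 with q 6.66e-11 in the authors' deposited table. Il1b (chromosome 2, 129364580 to 129375733) stood at 57.9 and 5.30 FPKM, with a fold of 3.45 ± 0.50 and q 6.41e-10 in the authors' deposited table. Cxcl2 (chromosome 5, 90903899 to 90905938) reached 123 FPKM against 8.64, with a fold of 3.83 ± 0.46 and q 5.49e-14 in the authors' deposited table. Folds in the same table were 4.33 for Cxcl1, 3.90 for Cxcl3, 3.06 for Il1a and 1.45 for Tnf, the tumor necrosis factor gene. Tnf, Il1a, Il1b and Csf2 entered the list with knowledge of the study, so their share of this count, here and in the comparisons that follow, is not independent evidence. Targets of NF-kB, the transcription factor that drives many of these cytokines, gave 13 higher and 0 lower of 20 with a median of 2.25 in the authors' deposited table. Among them were Cd83, a maturation marker of antigen-presenting cells, at 2.86, the survival gene Bcl2a1b at 2.61, the NF-kB subunit gene Rel at 2.62 and the adhesion receptor gene Icam1 at 2.28.

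**Figure D2:**
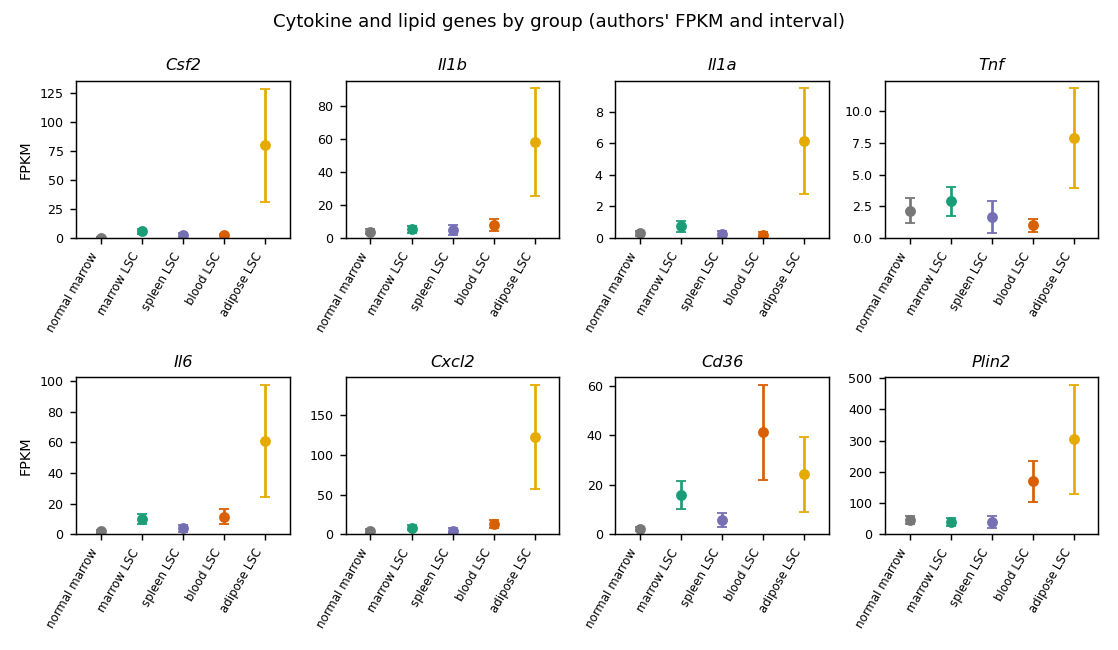
FPKM (y axis) of Csf2, Il1b, Il1a, Tnf, Il6, Cxcl2, Cd36 and Plin2 in the 5 groups (x axis), each point the authors' pooled value and each bar their interval. Csf2 stood at 79.8 FPKM in AT LSC and between 0.286 and 6.0 elsewhere, while Cd36 was at 24.4 in AT LSC and 41.3 in BL LSC.

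The largest gains among called genes with a mean CPM of 16 or more included genes of innate immune sensing and uptake. The folds in the authors' deposited table were 7.60 for Marco, a scavenger receptor (chromosome 1, 120474538 to 120505084), 5.34 for Aqp3, a channel for water and glycerol, and 4.69 for Irg1, which makes itaconate in activated macrophages. They were 4.58 for Cd14, a co-receptor for lipopolysaccharide, and 4.31 for Slc11a1, a metal transporter of phagosomes, in the authors' deposited table. Gpr137b and its pseudogene Gpr137b-ps, which share sequence, had folds of 4.40 and 4.40 there. Dcn, a matrix proteoglycan of fibroblasts, was listed at 21.0 FPKM in AT LSC and 0.0232 in BM LSC, the latter from fewer than 3 estimated fragments.

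Lipid uptake and storage genes gave 8 higher and 1 lower of 18 (9 and 1 adjusted over the list alone) in the authors' deposited table, with a median of 1.63. Plin2 (chromosome 4, 86656565 to 86670059) stood at 304 FPKM against 40.8, a fold of 2.90 ± 0.47 with q 3.35e-08 in the authors' deposited table. The folds there were 3.74 for Fabp4, 2.61 for Lpl and 2.71 for Dgat1, which completes triglyceride synthesis. Cd36, the fatty acid transporter placed in this list with knowledge of the study, stood at 24.4 and 15.9 FPKM and was not called, at 0.61 with q 0.468 in the authors' deposited table. Fatty acid oxidation genes did not move as a group, at 1 higher and 5 lower of 23 in the authors' deposited table. They gave 2 and 0 after centring, where the direction flipped, as it did under upper quartile and total count scaling. Cpt2 at -1.44, Decr1 at -1.41 and Hadh at -1.33, enzymes of this pathway, were called in the authors' deposited table, whereas Cpt1a, its entry step, was at -0.31 and was not. None of these 4 was called after centring. Pdk4, which restrains pyruvate oxidation, was listed at 0.523 FPKM in AT and 0.0247 in BM LSC.

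Other metabolic lists had few called genes in the authors' deposited table. Glycolysis gave 1 higher and 2 lower of 17 (1 and 0 adjusted over the list alone) and 1 and 0 after centring, a flipped direction. Oxidative phosphorylation gave 0 higher and 0 lower of 23. Cholesterol synthesis gave 0 higher and 4 lower of 16 and, flipped, 2 and 1 after centring, but 0 and 3 under total count scaling. Slc16a3, the lactate exporter, was at 1.86, Hk1 at -1.24 and the sterol enzyme genes Lss and Dhcr7 at -1.85 and -1.56 there, and of these Hk1 and Dhcr7 were not called after centring. Ndufs1 of respiratory complex I was at -0.97 in the authors' deposited table and was not called.

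Proliferation genes were lower in AT LSC on the authors' scale and less so on others. The authors' deposited table gave 0 higher and 13 lower of 25 (0 and 19 adjusted over the list alone) for the cell cycle list, 0 and 3 after centring and 0 and 6 under total count scaling, with a median of -0.73. The mitotic genes Bub1b at -2.21, Aurka at -1.86 and Plk1 at -1.79 were called there, and the proliferation marker Mki67 at -1.0 was not. Cell cycle inhibitors gave 5 higher and 1 lower of 14 in the authors' deposited table, led by Gadd45b at 2.32, a stress-induced brake, and Btg1 at 2.07, an antiproliferative gene. Myc, a driver of growth, was at -1.60 and was not called after centring.

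Stem and progenitor genes gave 0 higher and 9 lower of 19 (0 and 11 adjusted over the list alone) in the authors' deposited table and 0 and 3 after centring. Meis1 stood at 3.20 and 12.1 FPKM, with a fold of -1.92 in the authors' deposited table. The hematopoietic factor genes Tal1 and Erg were at -2.90 and -1.69 there, the latter not called after centring. Hoxa9 at -0.47 and the homing receptor gene Cxcr4 at 0.19 were not called in the authors' deposited table, and Kit had no test result, at 1.64 FPKM in AT and 2.93 in BM LSC. Megakaryocyte genes gave 0 higher and 6 lower of 8 (0 and 7 adjusted over the list alone). Erythroid genes gave 0 higher and 6 lower of 11. Mast cell and basophil genes gave 0 higher and 5 lower of 9 (0 and 6 adjusted over the list alone). After centring these became 0 and 5 for megakaryocyte, 0 and 3 for erythroid and 1 and 3 for mast cell genes. Folds in the authors' deposited table were -3.16 for the platelet factor gene Pf4, -2.99 for the erythroid carbonic anhydrase gene Car1 and -4.25 for the mast cell tryptase gene Tpsb2.

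The largest losses in AT LSC, chosen in the same way, included an endogenous retroviral gene and a platelet receptor gene. The folds in the authors' deposited table were -4.26 for the retroviral Erv3 (chromosome 2, 131853678 to 131859747), -4.14 for Art4, a blood group carrier, and -3.63 for Apoa1, of high density lipoprotein. They were -3.60 for Gp1ba, a platelet adhesion receptor, -3.57 for Ciita, the activator of MHC class II genes, and -3.45 for Nudt7, a peroxisomal coenzyme A hydrolase. Tph1, which starts serotonin synthesis, was at -3.42 and Gcsam, a lymphoid signalling gene, at -3.40 in the authors' deposited table.

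Myeloid granule genes gave 8 higher and 1 lower of 15 in the authors' deposited table, with folds of 2.24 for the antimicrobial Camp, 2.41 for the granule gene Ngp, 2.06 for S100a8 and 2.10 for S100a9. Adhesion and homing genes gave 5 higher and 0 lower of 18. Esam, an adhesion gene that endothelial cells also carry, was at 3.27, Cd44 at 2.09 and the integrin gene Itgam at 1.91 in the authors' deposited table. Immediate early genes gave 6 higher and 1 lower of 19. NRF2 targets with efflux pumps gave 3 higher and 1 lower of 15 (3 and 2 adjusted over the list alone). Hypoxia genes gave 2 higher and 2 lower of 19, with a median below 0 and a mean above it on the authors' scale. Heat shock genes gave 1 higher and 3 lower of 13, a direction that flipped under upper quartile scaling. Hmox1, the heme oxygenase gene, was at 3.76, the immediate early genes Nr4a1 and Klf4 at 2.26 and 2.23, and the mitochondrial chaperone Hspe1 at -1.62 in the authors' deposited table, the last not called under upper quartile scaling. Interferon response genes gave 0 higher and 4 lower of 18 (1 and 7 adjusted over the list alone) and, after centring, 2 and 0, so their direction flipped with the scaling. Antigen presentation genes gave 0 higher and 2 lower of 15 in the authors' deposited table.

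Markers of other cell types also moved in this comparison. Stromal genes gave 8 higher and 0 lower of 12 (8 and 1 adjusted over the list alone) in the authors' deposited table. Macrophage genes gave 6 higher and 1 lower of 11 (6 and 2 adjusted over the list alone). Mature neutrophil genes gave 4 higher and 0 lower of 10 (5 and 0 adjusted over the list alone). Adipocyte genes gave 3 higher and 1 lower of 8. Endothelial genes gave 3 higher and 0 lower of 10. B cell genes gave 1 higher and 0 lower of 7. T and NK cell genes gave 2 higher and 3 lower of 13 (2 and 4 adjusted over the list alone). Mesothelial or epithelial genes gave 1 higher and 0 lower of 4 there, with a negative median and a positive mean. The matrix gene Sparc was at 5.39, the CSF1 receptor gene Csf1r at 2.76, lysozyme gene Lyz2 at 2.82, the neutrophil receptor gene Trem1 at 2.87 and the adipocyte regulator Pparg at 2.83 in the authors' deposited table. Levels in AT LSC were 4.55 FPKM for Sparc and 5.84 for Pparg, whereas Lyz2 stood at 852.

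Against spleen, AT LSC carried cytokine and lipid genes at higher levels and lymphoid and erythroid genes at lower levels. Il6, the inflammatory cytokine gene, Csf2 and the fatty acid transporter gene Cd36 were higher in AT LSC, and Car1 and Slamf1, a surface receptor of stem and lymphoid cells, were lower. Of 12839 tested genes, 3219 were called in the authors' deposited table, 924 higher and 2295 lower. Centring the folds on their median of -0.52 gave 1472 higher and 892 lower (1516 and 887 under total count scaling). Cytokines gave 15 higher and 0 lower of 20 (17 and 0 adjusted over the list alone). The lipid list gave 12 higher and 1 lower of 18. Markers of other cell types moved with them, stromal genes at 7 higher and 1 lower of 12 (7 and 2 adjusted over the list alone), mature neutrophil genes at 6 higher and 0 lower of 10 (7 and 0 adjusted over the list alone) and macrophage genes at 4 higher and 1 lower of 11 (5 and 1 adjusted over the list alone). Erythroid genes gave 0 higher and 7 lower of 12 (0 and 8 adjusted over the list alone). Immediate early genes gave 12 higher and 0 lower of 19 (13 and 0 adjusted over the list alone). Folds in the authors' deposited table were 4.99 for Csf2, 3.97 for Il6, 4.74 for Il1a and 2.22 for Tnf. Cd36 was at 2.05 ± 0.57 with q 0.00297 and the lipid droplet gene Hilpda at 2.84 there. Among the largest gains of this comparison were Marco at 5.47, the membrane protein gene Emp1 at 5.28 and Aqp3 at 5.20 in the authors' deposited table. The largest losses were Slamf1 at -4.90, the immunoglobulin chain gene Igj at -4.84, the collagen gene Col5a1 at -4.82, Car1 at -4.74 and Art4 at -4.68 in the authors' deposited table. B cell genes gave 0 higher and 6 lower of 9 (0 and 7 adjusted over the list alone). T and NK cell genes gave 0 higher and 7 lower of 14 (0 and 9 adjusted over the list alone), but 0 and 3 after centring, 2 and 3 under upper quartile and 1 and 3 under total count scaling. The cell cycle list gave 0 higher and 16 lower of 25 (0 and 18 adjusted over the list alone) and 0 and 7 after centring. The B cell antigen Ms4a1 was listed at 3.22 FPKM in SPL LSC and 0.0111 in AT LSC.

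AT LSC and circulating LSC overlapped in their difference from marrow, yet cytokine, granule and cell cycle genes separated them. Mpo, the myeloperoxidase gene of immature granulocytes, Csf2, and Rrm2 and Cdk1, genes of DNA synthesis and mitosis, were higher in AT LSC, and Cx3cr1, a receptor of patrolling monocytes, was lower. Of 13042 tested genes, 850 were called in the authors' deposited table, 523 higher and 327 lower. Centring the folds gave 572 higher and 215 lower (721 and 149 under total count scaling). Cytokines gave 13 higher and 0 lower of 21 (14 and 0 adjusted over the list alone). Granule genes gave 8 higher and 0 lower of 15 (9 and 0 adjusted over the list alone). The cell cycle list gave 12 higher and 0 lower of 25 (17 and 0 adjusted over the list alone), with a median of 1.40 and 13 and 0 after centring. Folds in the authors' deposited table were 4.85 for Csf2, 2.97 for Tnf, 2.88 for Il1b and 4.60 for Irg1. Mpo (chromosome 11, 87793784 to 87804412) stood at 113 FPKM in AT and 6.23 in BL LSC, a fold of 4.19, and the granule regulator Cebpe was at 2.84 in the authors' deposited table. Rrm2 was at 1.66 and Cdk1 at 1.62, while Mki67 at 1.17 was not called in the authors' deposited table. Vcam1, an adhesion receptor of vessels and stroma, was at 5.14, but it was lower in BL than in BM and SPL LSC too. Stromal genes gave 9 higher and 0 lower of 12 in the authors' deposited table. The largest losses in the authors' deposited table were Ciita at -2.89, Cx3cr1 at -2.50, the channel gene Calhm2 at -2.38, the RNA regulator Zc3h12d at -2.35 and the TIFA inhibitor Tifab at -2.30. Lipid genes gave 3 higher and 0 lower of 18. Immediate early genes gave 5 higher and 0 lower of 19, endothelial genes 3 higher and 0 lower of 10 (7 and 0 adjusted over the list alone) and heat shock genes 0 higher and 0 lower of 13, the last with a median of 0.86 that 0 of 10000 random lists reached. Macrophage genes gave 0 higher and 1 lower of 10 (0 and 0 adjusted over the list alone), and Cd36 at -0.76 was not called in the authors' deposited table. B cell genes gave 0 higher and 3 lower, megakaryocyte genes 0 and 3, T and NK cell genes 0 and 2 and mature neutrophil genes 3 and 2. For these lists the counts adjusted over the list alone are not given.

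Genes called in the same direction against all 3 other leukemic sites numbered 185 higher and 42 lower of 12666 tested in each comparison of the authors' deposited table. Independent calls would give 2.87 and 7.43, although the shared AT values raise the overlap by themselves. The lower count depended on the scaling, at 19 after centring, 18 under upper quartile and 11 under total count scaling, where the higher counts were 232, 235 and 255, and adjustment within each comparison gave 146 and 11. The cytokine list supplied 9 of the 185 (Tnf, Il1a, Il1b, Il6, Csf2, Cxcl1, Cxcl2, Cxcl3 and the prostaglandin synthase gene Ptgs2), the granule list 6 and the stromal list 6. The mature neutrophil list supplied 3 (S100a8, S100a9 and Stfa2l1), and S100a8 and S100a9 also count among the granule genes. The endothelial list supplied 2 (Cdh5 and Ptprb). Matrix genes outside the lists, such as Bgn, Eln, Lox and Fbln2, were also among the 185. So were vessel genes outside the endothelial list, such as Ecscr, Mmrn2, Gja4 and Esam. These genes were picked after their values were seen. Stromal cells, endothelial cells and mature neutrophils in the adipose preparation are not excluded as a source of part of this set. Endothelial cells and neutrophils were not tested. By the mean of the 3 folds in the authors' deposited table, the leading genes were Marco at 5.30, Csf2 and Irg1 at 4.52, Cxcl2 at 3.89 and Cxcl3 at 3.88. The lowest were Ciita at -3.53, Nudt7 at -2.95, the interferon-induced GTPase gene Tgtp1 at -2.57, Calhm2 at -2.37 and the red cell enzyme gene Bpgm at -2.11.

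**Figure D3:**
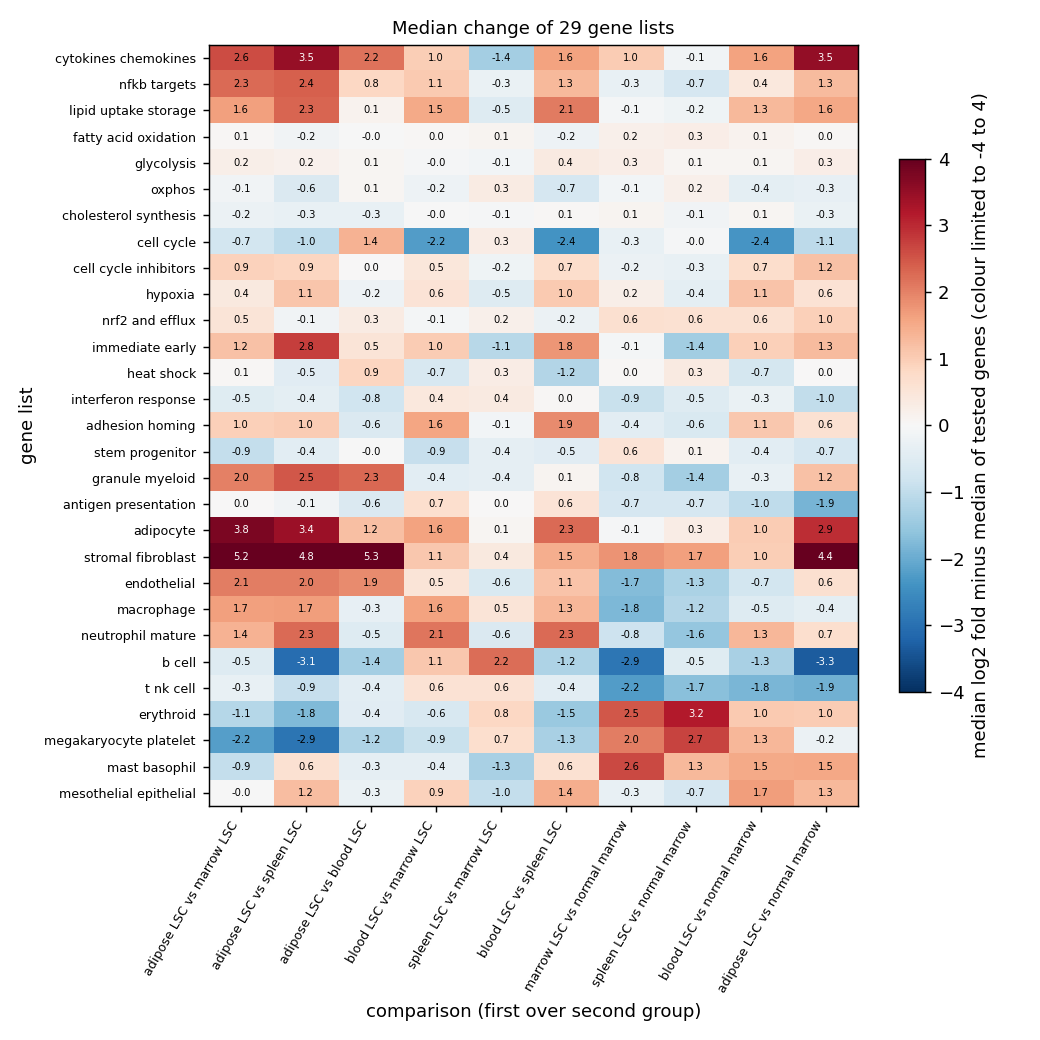
Median log2 fold of each gene list (y axis) in each of the 10 comparisons (x axis) of the authors' deposited table, relative to the median of all tested genes, with colour limited to 4 on either side. Cytokines stood at 2.60 in AT against BM LSC, and the cell cycle list at -2.23 in BL against BM LSC.

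Proliferation genes were lower in circulating than in marrow LSC, and genes of the macrophage and mature neutrophil lists higher. Plk1, Aurka and Top2a, which drive or accompany mitosis, E2f8, a cell cycle transcription factor, and Mpo were lower in BL LSC. Csf1r, Trem1 and the monocyte receptor gene Cd300e were higher. Of 12784 tested genes, 4253 were called in the authors' deposited table, 1343 higher and 2910 lower. Centring the folds on their median of -0.37 gave 1993 higher and 1725 lower (1444 and 2636 under total count scaling). The cell cycle list gave 0 higher and 22 lower of 25 (0 and 23 adjusted over the list alone) in the authors' deposited table, 0 and 20 after centring, and 0 of 10000 random lists had a median as low as its -2.23. Mki67 (chromosome 7, 135689788 to 135716379) stood at 2.90 FPKM in BL and 13.0 in BM LSC, a fold of -2.16 ± 0.37 with q 1.84e-07 in the authors' deposited table. Plk1 was at -3.17, Aurka at -3.16, Top2a at -2.96, E2f8 at -3.95 and Myc at -2.51 there. Adhesion genes gave 10 higher and 1 lower of 18 (11 and 1 adjusted over the list alone). Mature neutrophil genes gave 7 higher and 0 lower of 10 (8 and 0 adjusted over the list alone). Macrophage genes gave 5 higher and 0 lower of 11 (6 and 1 adjusted over the list alone). Lipid genes gave 8 higher and 1 lower of 18 (9 and 1 adjusted over the list alone). Csf1r was at 4.0, Trem1 at 3.34, Itgam at 2.76 and Cd44 at 2.56 in the authors' deposited table. Cd36 stood at 41.3 FPKM in BL LSC, a fold of 1.38 ± 0.42 with q 0.00817 in the authors' deposited table, and Fabp4 was at 3.20. The largest gains there were Aqp3 at 6.44, the tubulin-binding gene Tppp3 at 6.04, Cd300e at 5.69, the angiotensin-converting enzyme gene Ace at 5.24 and Trim43c at 4.96. The largest losses in the authors' deposited table were Vcam1 at -5.27, Mpo at -4.10, the eosinophil peroxidase gene Epx at -3.98 and E2f8. Cytokines gave 3 higher and 5 lower of 20 in the authors' deposited table and 6 and 1 after centring, where their direction flipped. Under total count scaling they gave 3 and 4, without a flip. Tnf at -1.52 and Csf2 at -1.11 were lower in BL LSC on the authors' scale and not called after centring. Stem genes gave 1 higher and 10 lower of 19 (1 and 11 adjusted over the list alone) on the authors' scale and 1 and 5 after centring. Lineage lists fell as well on the authors' scale. Erythroid genes gave 1 higher and 6 lower of 12, megakaryocyte genes 1 higher and 5 lower of 9 (2 and 5 adjusted over the list alone) and mast cell genes 1 higher and 4 lower of 9. After centring these became 1 and 5 for erythroid, 2 and 3 for megakaryocyte and 1 and 4 for mast cell genes. Immediate early genes gave 5 higher and 4 lower of 19 (8 and 4 adjusted over the list alone). Heat shock genes gave 0 higher and 6 lower of 12. The stem cell regulators Myb at -3.30 and Gata2 at -2.19 and the chaperone gene Hspd1 at -2.23 were lower in the authors' deposited table. Both AT and BL LSC differed from BM LSC in the same direction in 588 genes higher and 1519 lower of 12505 tested, where independent calls would give 81.7 and 475 and the shared BM values raise the overlap by themselves. In opposite directions, 5 genes were called. These were Csf2, Il1a, Tnf, the glutathione-degrading enzyme gene Chac1 and Serpinf1, an inhibitor of vessel growth, all higher in AT and lower in BL LSC, and the last 2 were picked out after their values were seen.

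**Figure D4:**
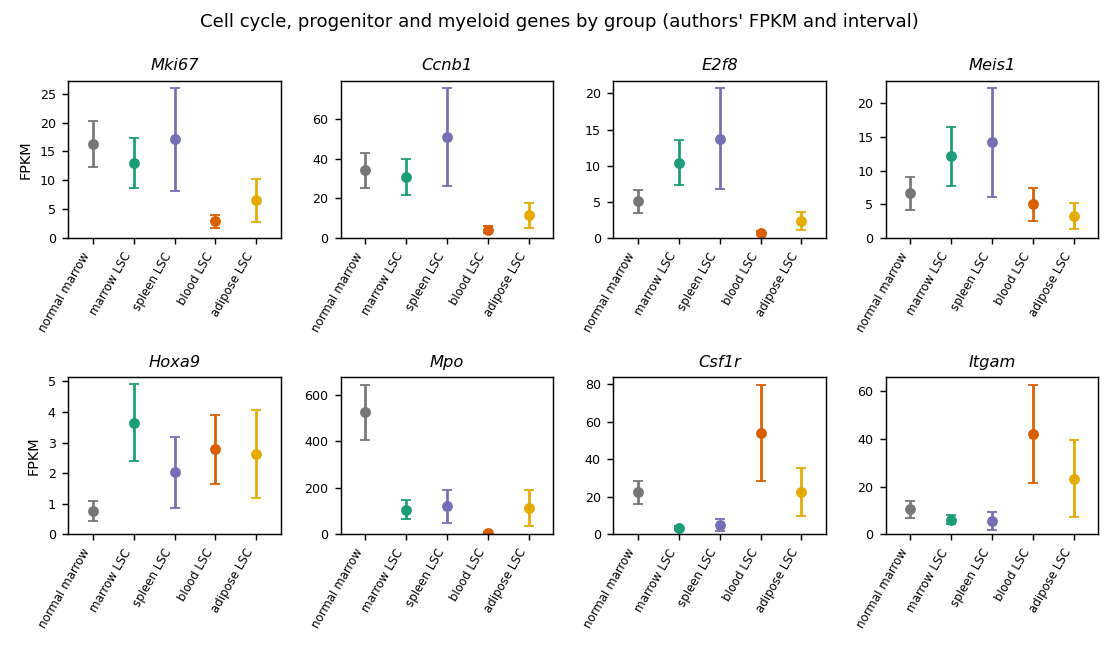
FPKM (y axis) of Mki67, Ccnb1, E2f8, Meis1, Hoxa9, Mpo, Csf1r and Itgam in the 5 groups (x axis), each point the authors' pooled value and each bar their interval. Mki67 stood at 2.90 FPKM in BL LSC and 17.1 in SPL LSC, and Mpo at 6.23 in BL LSC and 524 in NBM.

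Spleen and marrow LSC differed in the fewest genes, and the differences included lymphoid, mast cell, cytokine and immediate early genes. Ccr7, the lymphoid homing receptor gene, and Cd2, an adhesion receptor of T cells, were higher in SPL LSC, and the mast cell protease genes Tpsb2 and Cpa3 and the stress-induced pseudokinase gene Trib3 were lower. Of 12040 tested genes, 324 were called in the authors' deposited table, 143 higher and 181 lower. Centring the folds on their median of 0.12 gave 109 higher and 228 lower (91 and 308 under total count scaling). B cell genes gave 5 higher and 0 lower of 9 (6 and 0 adjusted over the list alone). Mast cell genes gave 0 higher and 5 lower of 9. Immediate early genes gave 0 higher and 8 lower of 19. Cytokines gave 1 higher and 8 lower of 19 (1 and 10 adjusted over the list alone). T and NK cell genes gave 4 higher and 0 lower of 13 in the authors' deposited table and 2 and 0 after centring, and the cell cycle list gave 0 higher and 0 lower of 25. Folds in that table were 3.09 for Ccr7, 2.84 for Cd83, 2.70 for the nuclease gene Dnase1l3, 2.62 for Cd300e and 2.45 for Cd2. They were -2.90 for Erv3, -2.61 for the actin-binding gene Avil, -2.39 for Trib3, -2.12 for the quiescence factor Klf2 and -2.09 for Rgs1, which damps chemokine signals, in the authors' deposited table. Tpsb2 was at -4.97, Cpa3 at -1.62 and Fos at -1.80 there. Other cells in the spleen preparation could give the lymphoid markers higher in SPL LSC. This was not tested here or against AT and BL LSC. Cd36 was at -1.43 ± 0.43 with q 0.00648 in the authors' deposited table, and was not called when p was adjusted within the comparison.

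Cell cycle genes were lower in circulating than in spleen LSC, and adhesion and lipid genes higher. The gap junction gene Gja1 and the interferon-induced GTPase gene Iigp1 were lower in BL LSC, and Klf2 and Osm, which encodes the cytokine oncostatin M, were higher. Of 12370 tested genes, 4122 were called in the authors' deposited table, 1264 higher and 2858 lower. Centring the folds on their median of -0.40 gave 1846 higher and 1794 lower (1648 and 2059 under total count scaling). Cell cycle genes gave 0 higher and 23 lower of 25 (0 and 24 adjusted over the list alone). Adhesion genes gave 11 higher and 1 lower of 18. Lipid genes gave 10 higher and 2 lower of 18. Erythroid genes gave 0 higher and 9 lower of 12. Among markers of other cells and of handling, mature neutrophil genes gave 6 higher and 0 lower of 10 (8 and 0 adjusted over the list alone), macrophage genes 4 higher and 1 lower of 11, B cell genes 0 higher and 4 lower of 9 (0 and 6 adjusted over the list alone), immediate early genes 7 higher and 1 lower of 19 (11 and 3 adjusted over the list alone) and heat shock genes 0 higher and 7 lower of 12 (0 and 8 adjusted over the list alone). Cytokines gave 7 higher and 1 lower of 20 (9 and 1 adjusted over the list alone). Folds in the authors' deposited table were 6.30 for Aqp3, 6.12 for Emp1, 4.06 for Klf2, 3.25 for Osm and 2.81 for Cd36. They were -6.41 for Vcam1, -5.22 for Iigp1, -4.98 for Gja1, -4.92 for Igj and -2.56 for Mki67. Trim43a and Trim43b, paralogs that share sequence, were at 6.76 and 6.61 in the authors' deposited table.

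Marrow LSC differed from normal marrow cells in lineage genes, in Hoxa9 and in antigen presentation, while no gene of the cell cycle list was called. Hoxa9, the gene fused to NUP98 in this model, the erythroid and mast cell factor gene Gata2, and Cdkn2b, a cell cycle inhibitor, were higher in BM LSC. The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1, the invariant chain gene Cd74, the T cell genes Cd3e and Cd4 and Cxcr4, the receptor that holds cells in the marrow, were lower. Of 12823 tested genes, 2053 were called in the authors' deposited table, 1047 higher and 1006 lower, and the median fold was -0.03. Hoxa9 (chromosome 6, 52224054 to 52227370) stood at 3.65 and 0.771 FPKM, a fold of 2.24 ± 0.40 with q 8.24e-07 in the authors' deposited table. Values per gene do not separate reads of the fusion from reads of the mouse's own Hoxa9. Meis1 at 0.87 and Myc at -0.23 were not called there, and Kit, at 2.93 and 10.4 FPKM, had no test result.

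The largest gains over NBM in the authors' deposited table were Erv3 at 7.0, the secretory protein genes Crisp1 and Crisp3 at 6.96 and 6.94, the matricellular gene Nov at 6.85 and the mast cell chymase gene Cma1 at 6.60. Psg21, of the pregnancy-specific glycoproteins, was at 5.80 there. The largest losses were the antigen receptor polymerase gene Dntt at -6.67, Cd3e at -5.16, the adhesion receptor gene Eltd1 at -5.13, the chemokine receptor gene Cxcr6 at -5.12 and Igj at -4.97 in the authors' deposited table. Cd2 at -4.55, the tryptophan enzyme gene Kmo at -4.50 and the costimulator gene Cd28 at -4.46 followed there.

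Mast cell and basophil genes gave 7 higher and 1 lower of 9 in the authors' deposited table. Erythroid genes gave 6 higher and 0 lower of 11. Megakaryocyte genes gave 6 higher and 1 lower of 8 (7 and 1 adjusted over the list alone). Folds there were 3.04 for Cpa3, 4.10 for the histamine enzyme gene Hdc, 2.85 for the erythroid factor Gata1, 2.32 for Car2, 2.83 for the platelet integrin gene Itga2b and 2.62 for Gata2. Antigen presentation genes gave 0 higher and 7 lower of 15 (0 and 8 adjusted over the list alone) in the authors' deposited table, with H2-Aa (chromosome 17, 34282751 to 34287771) at 57.3 and 523 FPKM and a fold of -3.19. H2-Ab1 was at -3.06, H2-Eb1 at -3.07 and Cd74 at -2.76 there. T and NK cell genes gave 3 higher and 10 lower of 14. B cell genes gave 0 higher and 7 lower of 10. Macrophage genes gave 1 higher and 9 lower of 12 (1 and 10 adjusted over the list alone). Interferon response genes gave 0 higher and 10 lower of 19 (0 and 11 adjusted over the list alone) in the authors' deposited table. Cd4 was at -4.33, the pre-B receptor gene Igll1 at -4.84, Csf1r at -2.73 and the interferon-induced Ifi44 at -3.77 there. Most markers called in the lymphoid and macrophage lists were thus lower along with the MHC class II genes. Other cells among the NBM cells could give this and were not tested. Here and in the other comparisons with NBM, it cannot be told apart from a change within LSC, which holds for Cxcr4 as well.

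Cxcr4 (chromosome 1, 128588199 to 128592299) stood at 1.98 FPKM in BM LSC and 20.2 in NBM, a fold of -3.35 in the authors' deposited table, and adhesion genes gave 0 higher and 5 lower of 18. The cell cycle list gave 0 higher and 0 lower of 25, with Mki67 at -0.32 in the authors' deposited table. Cytokines gave 8 higher and 3 lower of 20 (10 and 3 adjusted over the list alone) there, with Csf2 at 4.39, Il6 at 2.34 and the chemokine gene Ccl5 at -2.69. Tnf at 0.42, Il1a at 1.32 and Il1b at 0.50 were not called in the authors' deposited table. Cd36 stood at 15.9 and 2.16 FPKM, a fold of 2.88 ± 0.40 with q 8.70e-11 there, and the lipid list gave 2 higher and 2 lower of 19. NRF2 targets and efflux pumps gave 4 higher and 0 lower of 15, with the quinone reductase gene Nqo1 at 2.96 and the drug pump gene Abcg2 at 1.48 in the authors' deposited table. Stem genes moved both ways, at 6 higher and 5 lower of 21 (8 and 5 adjusted over the list alone), with Mycn at 2.74 and the stem cell factor Hlf at -2.66 there. Mpo was at -2.30, Cdkn2b at 3.80 and Cdkn2c at 1.69 in the authors' deposited table.

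Spleen LSC differed from normal marrow cells in many of the genes called in marrow LSC, with erythroid and megakaryocyte genes higher and MHC class II genes lower. Of 12498 tested genes, 1570 were called in the authors' deposited table, 796 higher and 774 lower. Centring gave 693 higher and 844 lower (586 and 1036 under total count scaling). Both BM and SPL LSC differed from NBM in the same direction in 621 genes higher and 624 lower of 12448 tested, with 0 in opposite directions. Independent calls would give 56.8 and 62.3 in the same direction, and the shared NBM values raise the overlap by themselves. Erythroid genes gave 8 higher and 0 lower of 12 (10 and 0 adjusted over the list alone). Megakaryocyte genes gave 7 higher and 0 lower of 8. Antigen presentation genes gave 0 higher and 7 lower of 15, beside T and NK cell genes at 3 higher and 8 lower of 14 and macrophage genes at 1 higher and 4 lower of 12 (1 and 6 adjusted over the list alone). Immediate early genes gave 0 higher and 8 lower of 19 (0 and 11 adjusted over the list alone) there. Car1 was at 4.19, the erythropoietin receptor gene Epor at 4.07, the platelet adhesion gene Vwf at 3.79, H2-Eb1 at -2.65 and Fos at -2.48 in the authors' deposited table. C1qtnf1, a complement-related secreted protein gene, had the largest gain at 5.87, and Nov was at 5.20, Cma1 at 5.06 and Crisp1 at 5.05 there. Dntt at -7.0, Eltd1 at -6.64 and the leukemia-linked Mn1 at -4.59 led the losses in the authors' deposited table. Hoxa9 was at 1.40, Kit, the stem cell factor receptor gene, at -1.34, Cd36 at 1.45 and Cxcr4 at -2.78 there. Of these, Hoxa9 was not called after centring and Cd36 not under total count scaling.

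Circulating LSC differed from normal marrow cells in the most genes, with proliferation lower and lipid and cytokine genes higher. Of 13020 tested genes, 4474 were called in the authors' deposited table, 1494 higher and 2980 lower. Centring the folds on their median of -0.36 gave 2162 higher and 1821 lower (1495 and 2873 under total count scaling). The cell cycle list gave 0 higher and 23 lower of 25 (0 and 24 adjusted over the list alone). Cytokines gave 9 higher and 2 lower of 21 (11 and 3 adjusted over the list alone). Lipid genes gave 8 higher and 2 lower of 19. Stem genes gave 2 higher and 10 lower of 22. Markers of other cells moved too, with mature neutrophil genes at 4 higher and 0 lower of 10 (4 and 1 adjusted over the list alone). T and NK cell genes gave 1 higher and 9 lower of 14 (2 and 10 adjusted over the list alone). B cell genes gave 0 higher and 6 lower of 10, and 0 and 3 after centring. Macrophage genes gave 4 higher and 5 lower of 12 (4 and 6 adjusted over the list alone) and antigen presentation genes 0 higher and 9 lower of 15 (1 and 9 adjusted over the list alone). Heat shock genes gave 1 higher and 6 lower of 12 (1 and 9 adjusted over the list alone). Folds in the authors' deposited table were -2.48 for Mki67, -3.18 for Top2a, 4.26 for Cd36, 3.43 for Osm and 3.42 for the chemokine gene Ccl9. Mpo, at 524 FPKM in NBM, was at -6.39, Igj at -8.12, Eltd1 at -8.16 and Kmo at -6.35 there. Nov at 7.96 and the vomeronasal receptor gene Vmn2r19 at 7.13 were among the largest gains of genes counted in both groups in the authors' deposited table. Dntt was listed at 0.00429 FPKM in BL LSC and 31.8 in NBM.

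Cytokine genes were higher in AT LSC than in normal marrow cells, and antigen presentation genes lower. Of 13346 tested genes, 3127 were called in the authors' deposited table, 1060 higher and 2067 lower. Centring the folds on their median of -0.46 gave 1650 higher and 876 lower (1362 and 1285 under total count scaling). Cytokines gave 17 higher and 1 lower of 20 with a median of 3.53. Antigen presentation genes gave 0 higher and 10 lower of 15 (0 and 11 adjusted over the list alone). Markers of other cells went both ways. Lower were B cell genes at 0 higher and 8 lower of 10 (1 and 9 adjusted over the list alone), T and NK cell genes at 1 higher and 9 lower of 14 and macrophage genes at 2 higher and 5 lower of 12 (2 and 6 adjusted over the list alone), the last 3 and 3 after centring. Adipocyte genes gave 4 higher and 1 lower of 8, mature neutrophil genes 3 higher and 1 lower of 10 and mast cell genes 3 higher and 1 lower of 9 (4 and 1 adjusted over the list alone). Immediate early genes gave 7 higher and 2 lower of 19. Stromal genes gave 10 higher and 0 lower of 12 (11 and 0 adjusted over the list alone). Cell cycle genes gave 0 higher and 18 lower of 25 (0 and 19 adjusted over the list alone) and 0 and 8 after centring. Csf2 was at 8.12, Il6 at 4.97, Il1a at 4.38, Il1b at 3.95 and Tnf at 1.87 in the authors' deposited table. Marco at 9.21 was among the largest gains, and Igj at -8.03, Ciita at -6.98, Kmo at -6.85, the T cell surface gene Cd6 at -6.36 and the lymphoid antigen gene Ly6d at -6.20 led the losses there. Cd36 was at 3.49, Hoxa9 at 1.77, Kit at -2.66, Mki67 at -1.32 and Cxcr4 at -3.16 in the authors' deposited table, where Mki67 was not called after centring.

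All 4 LSC groups differed from NBM in the same direction in 528 genes, 234 higher and 294 lower of 12335 tested in each comparison of the authors' deposited table, where independent calls would give 0.298 and 2.52. The shared NBM values raise this overlap by themselves. Paralogs that share reads, such as the Psg and Vmn2r genes, are counted singly among the 234 and are not separate observations. The shared gains on the authors' scale included Hoxa9, Mycn, Cd36, Csf2, Nqo1, the cell cycle inhibitors Cdkn2a and Cdkn2b and the glucose transporter gene Slc2a3. Reads of the fusion may be counted in Hoxa9. The shared losses included Cxcr4, Mpo, Flt3, a progenitor receptor gene, Hlf, 7 antigen presentation genes and 7 T and NK cell genes. By the mean of the 4 folds in the authors' deposited table, Nov at 6.82, Crisp1 at 5.95, Crisp3 at 5.91, Cma1 at 5.83 and the steroid enzyme gene Akr1c18 at 5.58 led the gains. Eltd1 at -6.20, Igj at -6.07, Kmo at -5.55, Cxcr6 at -5.04 and Cd3e at -4.70 led the losses there.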

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

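The tests of macrophages, stromal cells and handling stress, and of scaling and dilution for the cell cycle genes, were chosen only after the result was seen, and those of scaling and of length and GC content after the excess of lower calls was seen but before the shares they gave.

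Some genes stood out because 2 leukemic sites differed from NBM in opposite directions, each called, and the direct comparison of the 2 sites was called as well. The folds below are of the first site over the second on the authors' scale. Between AT and BL LSC, 11 genes met this, and the folds of the named ones in the authors' deposited table were Camp at 3.07, Esam at 3.14, Gadd45b at 2.88 and Sparc at 6.41. For AT and BM LSC there were 43, with Ace at 4.27, Art4 at -4.14, Cd14 at 4.58, Esam at 3.27, Gcsam at -3.40, Gpr137b at 4.40, Gpr137b-ps at 4.40, Lyz2 at 2.82, Rel at 2.62, Slamf1 at -2.94 and Slc11a1 at 4.31 among the named genes in the authors' deposited table. AT and SPL LSC had 49, and the named genes stood at Art4 at -4.68, Emp1 at 5.28, Esam at 3.27, Klf2 at 2.91, Slamf1 at -4.90 and Trem1 at 3.65 in the authors' deposited table. Circulating against marrow LSC gave 103, and the authors' deposited table lists Ace at 5.24, Aqp3 at 6.44, Cd14 at 4.44, Cd300e at 5.69, Cd44 at 2.56, Csf1r at 4.0, Cx3cr1 at 2.46, E2f8 at -3.95, Gcsam at -3.03, Gpr137b at 3.32, Gpr137b-ps at 3.31, Lyz2 at 3.19, Slamf1 at -2.53 and Slc11a1 at 4.54. Against spleen, BL LSC had 110, and named genes in the authors' deposited table were Aqp3 at 6.30, Cd300e at 3.07, Csf1r at 3.43, E2f8 at -4.35, Emp1 at 6.12, Klf2 at 4.06, Slamf1 at -4.48 and Trem1 at 4.12. Gpr137b and Gpr137b-ps share sequence, so they are not separate observations. Sparc belongs to the stromal list, and other cells in the adipose preparation are not excluded for the genes higher in AT LSC. Tissue site was not tested as an explanation.

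More called genes were lower than higher in AT and in BL LSC than in BM LSC, at 68.2% and 68.4% of calls in the authors' deposited table. Removing the trend with transcript length and GC content, known for 93.6% of tested genes, left 67.7% and 69.2%. The removal kept the median fold of all genes, which itself sets much of the balance of directions. It therefore cannot decide on such a bias. Scaling is a candidate explanation for AT LSC, since the lower share became 43.1% under total count and 28.8% under upper quartile scaling. The 30.2% after centring is largely set by centring itself and was not counted. Upper quartile scaling shifted the folds by -0.498 in AT and -0.395 in BL against BM LSC, and centring by -0.477 and -0.366. The upper quartile shares therefore add little beyond centring. For BL LSC the shares were 64.6%, 44.2% and 46.4% in the same order, and because total count and upper quartile scaling fall on either side of an even split, scaling and a true loss of transcripts cannot be told apart there. A difference between tissues stays open as well and was not tested.

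Cytokine genes were higher in AT LSC than at each other site, and none of the tests run excludes cells of the adipose preparation other than LSC, which could be their source. Macrophages were judged by a list of 14 symbols, of which Adgre1 and Emr1 name the same gene. None was in another list, and 9 were at 1 FPKM or more in NBM. On the authors' scale the median fold was -0.43 in AT over BL LSC, with 0 members called higher. Over BM LSC it was 1.17, with 6 of 11 called higher and Cd163 called lower. The 6 gained 799 FPKM in all, most of it from Lyz2. Macrophages cannot be told apart from LSC maturation, because BL LSC already stood at 1105 FPKM for Lyz2 and 54.2 for Csf1r, against 852 and 22.9 in AT LSC, which would hide an added share. Marco and Irg1, the latter of activated macrophages, were also higher in AT than in BL LSC. Stromal genes moved with the cytokines, 8 of 13 (none in another list, 3 at 1 FPKM or more in BM LSC) called higher over BM LSC and led by Dcn at 21.0 FPKM, and their gain of 37.9 FPKM was 0.0824 of the 460 gained by 12 cytokine genes, which leaves stromal cells open since no table gives their own ratio. Handling stress stays open, as 5 of 19 immediate early and 0 of 13 heat shock genes (3 under total count scaling) were called higher in AT over BL LSC although the heat shock median of 0.76 on that scale passed all 10000 random lists, as does tissue site, and the labels name no gate that would remove other cells.

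Cell cycle genes were lower in BL than in BM LSC. The scaling is argued against as the cause, since the list median stayed at -2.23 after the median of tested genes was subtracted. Dilution by mature cells that do not cycle would lower stem and progenitor genes alike if those cells lacked them too. Of 19 tested members, 15 (78.9%, Wilson 95% bounds 56.7% to 91.5%) lay above the cell cycle median by more than the 95% bound of their own error. The Wilson bounds treat genes as independent, and the genes are few. No value here gives their level in mature cells, so this share cannot decide on dilution. Dilution and slower cycling in blood may both contribute, and tissue site itself was not tested.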

How the results depend on the processing

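Scalings, adjustment within the comparison, a q below 0.01, a mean CPM of 5 or more and the removal of shared loci were chosen after seeing the data, whereas the other alternatives were planned. List medians here are on the authors' scale. Under a q below 0.01, by construction stricter, called genes numbered 1596 for AT against BM, 1759 for AT against SPL, 382 for AT against BL, 148 for SPL against BM LSC, 1024 for SPL LSC against NBM and 1806 for AT LSC against NBM, with 111 shared by AT LSC against each other site and 351 by the 4 LSC groups against NBM. Adjustment within the comparison gave 398 for AT against BL and 106 for SPL against BM LSC, and the mean CPM filter, which tests fewer genes, gave 132 genes for AT LSC against each other site. The other total counts stayed within 1.5 times the reported ones, but counts in 1 direction moved further, under total count scaling from 327 to 149 lower in AT against BL, from 181 to 308 lower in SPL against BM and from 42 to 11 lower in AT against each other site. With the mean CPM filter, genes higher in AT fell from 185 to 91 against each other site and from 523 to 293 against BL. Adjustment within the comparison took those lower in AT against BL from 327 to 110. Leaving out members of other lists reversed the adipocyte median from 1.25 to -1.46 in BL against BM and from 1.86 to -2.00 in BL against SPL LSC, and the granule median from 0.70 to -0.18 in AT LSC against NBM; this tests fewer genes. Of 167 list medians outside 95% of random lists, 160 stayed outside in that setting, 163 with a pseudocount of 0.1 and 150 with 1. Of 228 called values of named genes, 11 were no longer called after centring, 12 under upper quartile and 7 under total count scaling, 9 at q below 0.01, 2 with adjustment within the comparison and 2 without a filter, and none changed sign. The cause was not tested. Of 14 values not called, 1 became called, Mki67 in AT against BL LSC under total count scaling. A pseudocount of 1 moved 131 of the 228 folds by more than their error, and 0.1 moved 34. SPL LSC had the fewest estimated counts, 8.96e+06, and AT against SPL LSC the largest median error, 0.585. The smallest fold called there was 1.26, and larger ones can be missed as well. No paired analysis was possible because the columns carry no replicate values. For the same reason edgeR, DESeq2, limma-voom, RLE factors, limma on log2 FPKM, fits of only the groups compared, leaving out a replicate, camera and fry were not run.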

Other observations

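The gene families and genes in this part were chosen only after their values were seen. Besides the listed programs, families of paralogs outside the gene lists stood apart, and their members share reads, so counts of members are not independent. Of 12 tested pregnancy-specific glycoprotein (Psg) genes, all 12 were called higher in BM LSC than in NBM in the authors' deposited table, with a median of 5.63. Their median was 4.11 in SPL, 3.75 in BL and 3.36 in AT LSC against NBM, with 12 of 12 called in each. Against BM LSC, all 12 were lower in SPL (-1.51), BL (-1.91) and AT LSC (-2.28) in the authors' deposited table. Psg21 stood at 11.9 FPKM in BM LSC, 4.28 in SPL, 4.38 in BL, 2.66 in AT LSC and 0.213 in NBM.

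Vomeronasal receptor genes (Vmn2r) were highest in the circulation, with 14 of 14 called higher in BL LSC than in NBM (median 6.92) and 14 of 15 higher than in BM LSC (2.60) in the authors' deposited table. AT LSC had 14 of 15 higher than BM LSC (1.28) and 8 of 14 lower than BL LSC (-1.30). The Trim43 genes followed them, with Trim43a at 8.29 FPKM in BL, 2.78 in AT, 0.291 in BM and 0.0765 in SPL LSC, and 0.00258 in NBM. Of 4 calcium-activated chloride channel regulators (Clca), 3 were called higher and 1 lower in SPL than in BM LSC in the authors' deposited table. Clca1 stood at 21.6 FPKM in SPL, 5.5 in BM, 1.87 in AT, 1.53 in BL LSC and 0.818 in NBM, and Clca3, the one lower in SPL, at 0.393 in SPL and 2.13 in BM LSC. The scalings shift all folds by between -0.58 and 0.27, which leaves the sign of each median given here.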
